A study of Mus musculus with 16 samples.

How the data were processed

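Small RNA sequencing was analysed for dendritic cells grown from the bone marrow of 8-week-old male C57BL/6 mice. Per the labels, red cells were lysed before culture. Cells received no treatment (control), lipopolysaccharide (LPS, a bacterial cell wall component that activates TLR4) at 1 µg/mL for 6 h on day 8, quercetin (a plant flavonol) at 25 µM on days 5 and 7, or quercetin followed by LPS. There were 4 groups of 4 libraries. Total RNA with its small RNAs was prepared with a miRNeasy kit and the libraries with a TruSeq Small RNA kit, per the labels.

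The deposited table holds counts of reads per mature miRNA, not normalised, for 16 libraries. Per the submitters' processing notes, the authors used cutadapt and the mouse genome build mm9; no version, aligner or counting rule is given in the sources used here. Names were taken from the table alone and no coordinates were used. The table has 1381 rows and 1377 names. Counts of 4 names that stand on 2 rows each were summed. For miR-363-3p, nearly all quercetin counts (mean 145.5, against 2.5) stood on a different row from those of the other groups. A row for miR-7236-5p, which held text among its counts, was left out. Also left out were 4 rows that form 2 pairs of neighbours (miR-6993-3p with miR-1839-5p, and miR-700-3p with miR-654-3p), since their counts in the libraries with quercetin look exchanged between the neighbours. They were found by a scan of 1378 neighbouring pairs and are described in the closing part. This left 1372 names. Among names with over 200 counts in all, 15 sets of 32 names carry identical counts in every library, such as miR-486a-5p with miR-486b-5p and miR-199a-3p with miR-199b-3p, so the reads of these copies cannot be assigned to either.

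Depth was the sum of counts per library, from 6459654 to 13949915. No libraries of the same group were near duplicates by a chi-square comparison of their counts, and pairs from different groups were not compared in this way. Tests used edgeR 4.0.16 in R 4.3.3: filterByExpr by group, which kept 568 miRNAs, TMM scaling, a quasi-likelihood fit to all 16 libraries with a coefficient per group, and Benjamini-Hochberg adjustment within each comparison with a threshold of 0.05. Adjusted p-values of single miRNAs are from this test unless another tool is named. Each standard error (SE) is the fold change on the log2 scale divided by the square root of the F statistic. Levels are CPM with TMM scaling, given as mean and SD over n = 4. Fold changes are relative to the TMM scale.

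Sets of miRNAs were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between miRNAs of 0.01, adjusted by Benjamini-Hochberg over the 17 lists of a comparison. Each was repeated with the correlation estimated from the data, and fry, also of limma and adjusted over the same 17 lists, was run beside it. It asks whether the members of a list move, on balance, one way and does not compare them with other miRNAs. The lists, written before the data were examined, were: LPS-induced miRNAs of myeloid cells; miRNAs described as falling after TLR4 stimulation; the let-7, miR-15/16, miR-29, miR-30 and miR-181 families; the miR-17-92 cluster with its paralogous clusters; the miR-23/27/24 clusters; the p53-induced miR-34 family with hypoxia-induced miR-210; the imprinted Dlk1-Dio3 cluster; the Sfmbt2 intronic cluster; granulocyte and monocyte miRNAs; and, as markers of other cell types, erythroid miRNAs, lymphocyte miRNAs, a list of stromal, endothelial and epithelial miRNAs, and tissue miRNAs foreign to bone marrow. Members past the threshold were counted after adjustment over all miRNAs and adjusted over the list alone.

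The rule for named miRNAs, also written before the data were examined, took miR-155-5p, miR-146a-5p and miR-369-3p always. It took the 12 largest rises and the 12 largest falls past the threshold with a mean of at least 10 CPM over the libraries compared, or the 5 smallest p-values where fewer than 5 passed. It also took up to 4 members per list and the 5 most abundant miRNAs of the controls. Other list members named in the text were chosen after their values were seen.

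The series design names 4 mice and the labels number the samples by mouse, so equal numbers were taken to mark the same animal. As a check, deviations from the group means were correlated across miRNAs. Over the 24 pairs of libraries from the same mouse the mean r was 0.14 (-0.47 to 0.65, 11 over 0.1), and over the 72 pairs from different mice -0.04 (-0.58 to 0.67, 21 over 0.1). All 3 same-mouse pairs of control 3 (-0.47 to -0.17) and of control 4 (-0.32 to -0.15) lay below 0, while control 3 correlated with the other libraries of mouse 4 at 0.67, 0.47 and 0.57. Of 24 exchanges of 2 libraries within a group, that of control 3 and control 4 gave the highest mean r, 0.31, so for these controls the labels and the correlations differ, and the labels were kept. The main test does not use the pairing. The fit with the mouse as a replicate block, which called 3, 92, 144 and 2 miRNAs in the 4 comparisons and 0 for the interaction, was an alternative. Other alternatives were RLE, upper quartile and library size scaling, other filters, DESeq2 1.42.0, limma-voom, a fit to only the groups compared, and leaving out each library. Added after the data had been seen were the block with control 3 and control 4 exchanged, the left-out rows as deposited or put back (also for the lists), identical names collapsed, thinning to the smallest library, removal of a trend on hairpin GC content, sample weights, and leaving out each mouse. Hairpin GC content was computed from GRCm38 sequences for 546 of the 568 miRNAs tested (96.1%) by name.

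The steps were tested on simulated counts with known changes, many at once. For LPS vs control, 64 miRNAs changed 1.5-fold, 66 changed 2-fold and 66 changed 4-fold, of 554. Far more changed than were called in the data for LPS vs control or the interaction. Adjustment is more lenient when more miRNAs change, so the shares below may overstate what could be recovered there. In LPS vs control, 7.81% of miRNAs changed 1.5-fold, 33.3% of those changed 2-fold and 87.9% of those changed 4-fold were recovered. For the interaction these shares were 0%, 13.8% and 71.2%. Smaller differences than these are mostly out of reach with 4 libraries per group. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.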

Results

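Mature miRNAs were counted in 16 small RNA libraries of mouse bone marrow dendritic cells: control, LPS, quercetin, and quercetin plus LPS, with 4 mice in each group. The most abundant miRNA of the control cells was miR-22-3p, at 15.03% ± 2.40 of counts (SD, n = 4). It was followed by miR-21a-5p (13.5% ± 2.26), miR-181a-5p (9.29% ± 1.72), miR-27b-3p (7.01% ± 1.37) and miR-146b-5p (6.72% ± 3.44), a relative of miR-146a with the same seed. In the quercetin group miR-146b-5p held 2.26% ± 0.686 of counts, and it did not pass in quercetin vs control over all miRNAs (edgeR). Its share was 9.50% ± 5.86 in LPS and 2.97% ± 2.28 in quercetin plus LPS libraries. Total counts averaged 10618224 ± 1592635 in control, 12228360 ± 1659799 in LPS, 8137368 ± 375563 in quercetin and 7835800 ± 1069702 in quercetin plus LPS libraries (SD, n = 4). They ran from 6459654 in quercetin plus LPS replicate 3 to 13949915 in LPS replicate 2. Totals were lower with quercetin both without and with LPS, each with an exact permutation p of 0.0286 (two-sided, libraries taken as unrelated) and 0.114 after Benjamini-Hochberg adjustment over 8 tests. Compared within mice, totals were lower in 4 of 4 with an exact sign permutation p of 0.125 each, the smallest that 4 mice can give. Between 825 and 999 miRNAs were detected per library. The first component of the log2 CPM took 34.2% of the variance and the second 22.0%. On the second component control 3 (12.2), LPS 4 (14.2), quercetin 4 (-2.64) and quercetin plus LPS 4 (15.0023) lay above the other libraries of their groups, which ran from -0.63 to 0.93, from 1.20 to 4.17, from -12.4 to -10.3 and from -11.4 to 6.99.

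**Figure D1:**
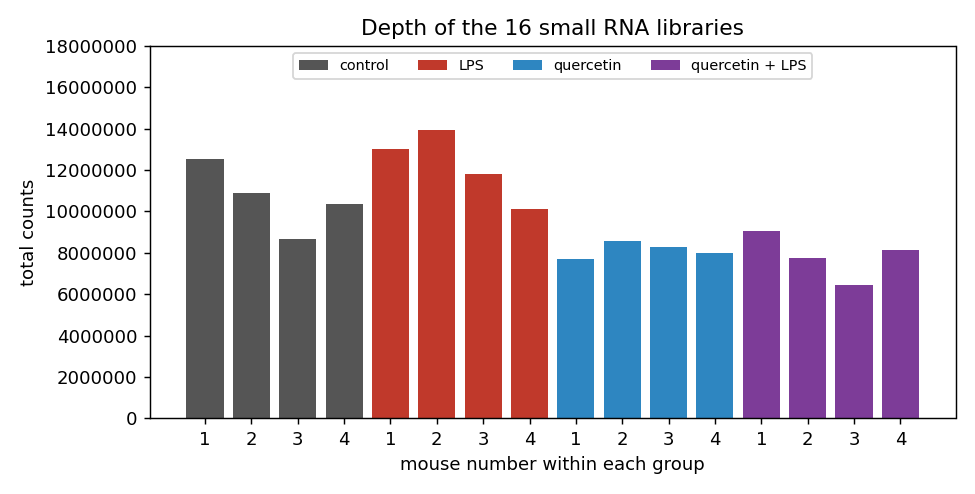
Total counts of each library (vertical axis, from 0), by mouse number within each group (horizontal axis), with bars coloured by group. Totals ran from 6459654 to 13949915, and the quercetin and quercetin plus LPS libraries averaged 8137368 and 7835800.

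The first comparison asked which miRNAs differ 6 h after LPS. miR-155-3p, the passenger arm of the hairpin that yields miR-155, a miRNA induced by Toll-like receptor signals, rose from 139 ± 57.6 to 556 ± 186 CPM (SD, n = 4), a log2 fold change of 2.00 ± 0.35 (SE, adjusted p = 0.0106 by edgeR), and was higher with LPS in 4 of 4 mice. miR-222-5p, from the miR-221/222 cluster, rose from 184 ± 42.6 to 409 ± 69.2 CPM (1.15 ± 0.21, adjusted p = 0.0106). miR-129-5p rose by 2.15 ± 0.42 (adjusted p = 0.0179), at a low level of 1.27 ± 0.245 CPM in controls and 5.71 ± 1.60 CPM after LPS. These 3 of 568 miRNAs passed the threshold and none fell by edgeR, while 26 had an unadjusted p under 0.05. DESeq2 called 5 higher and 1 lower, and limma-voom 2 higher and 1 lower.

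Other LPS-responsive miRNAs did not pass. The guide arm miR-155-5p was at 36162 ± 12340 CPM in controls and 49912 ± 14167 after LPS (log2 fold change 0.46 ± 0.30, adjusted p = 1.00), and miR-146a-5p, a feedback regulator of TLR signalling, at 1586 ± 1113 and 2789 ± 1953 CPM (0.81 ± 0.64, adjusted p = 1.00). miR-369-3p differed by -0.06 ± 0.43 (adjusted p = 1.00). miR-222-3p was 1.14 ± 0.26 higher (adjusted p = 0.0730) and miR-138-1-3p 1.60 lower (-1.60 ± 0.38, adjusted p = 0.0735), and miR-221-3p differed by 0.42 ± 0.20 (adjusted p = 0.965). In the list of LPS-induced miRNAs of myeloid cells, 1 of 20 members rose over all miRNAs and 2 when adjusted over the list alone. That list was shifted up relative to other miRNAs (camera adjusted p = 0.00994), with adjusted p = 0.422 with an estimated correlation. By fry, no list passed in this comparison (smallest adjusted p 0.451). The stromal, endothelial and epithelial list, markers of other cell types, had 0 of 17 members past the edgeR test and lay lower with a camera adjusted p of 0.0516, which was 0.0301 with the mouse as a block (adjusted p = 0.667 with an estimated correlation).

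Each LPS call was lost without some of the single libraries and kept without others. miR-155-3p was lost without control 1, 3 or 4 or LPS 1 or 2 (adjusted p 0.0503 to 0.0738, log2 fold change 1.72 to 2.03). miR-222-5p was lost without control 1, 2 or 4 or LPS 1, 2 or 4 (0.0503 to 0.0738), and miR-129-5p without any control or without LPS 1, 2 or 3 (0.0696 to 0.136). The shift of the LPS-induced list was lost without control 1 (adjusted p = 0.0793), control 4 (0.0529), LPS 1 (0.0984), LPS 2 (0.0738) or LPS 4 (0.0682). The median of all miRNAs was 0.02 with TMM and -0.13 with library size scaling.

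**Figure D2:**
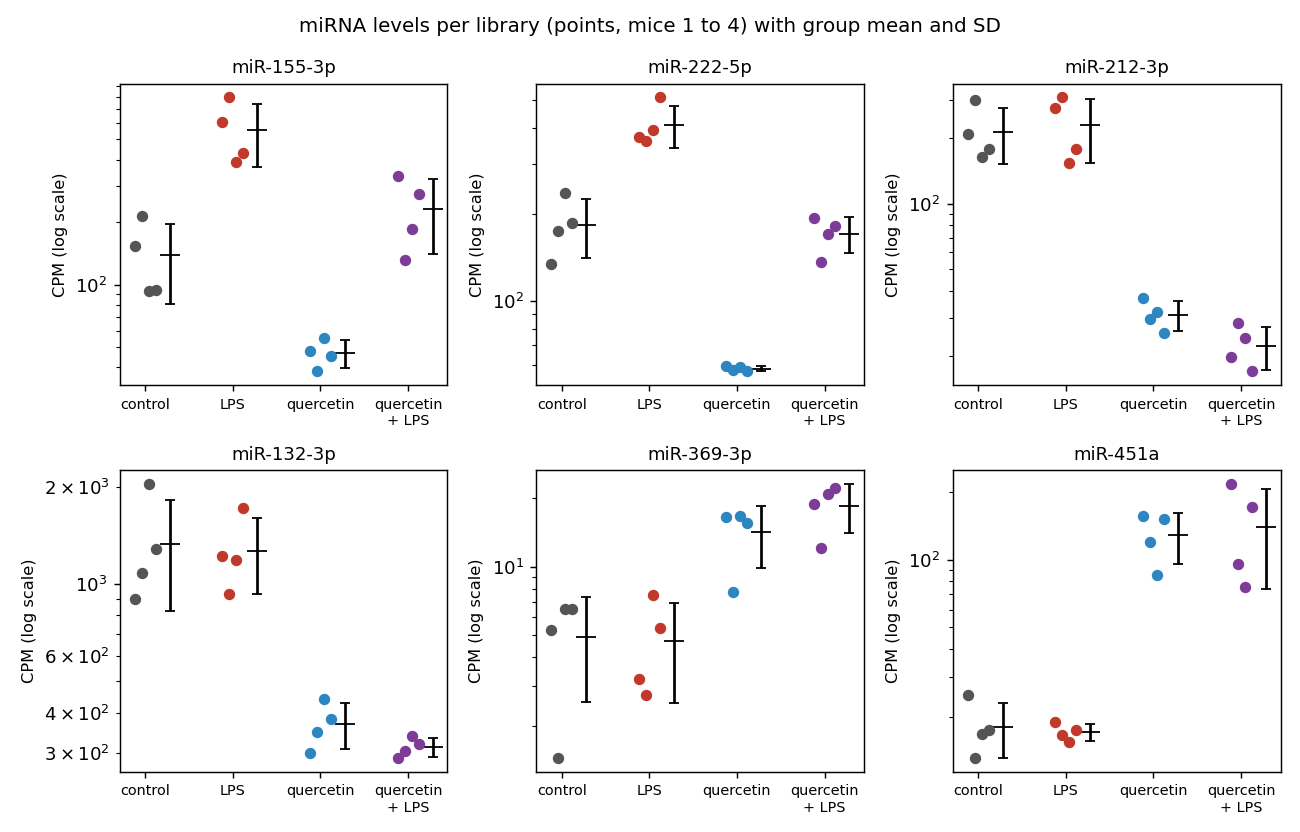
CPM (log axis) of miR-155-3p, miR-222-5p, miR-212-3p, miR-132-3p, miR-369-3p and miR-451a in the 4 groups. Points are single libraries, and the bar beside them is the mean with its SD (n = 4). miR-155-3p averaged 139 CPM in control, 556 in LPS, 46.9 in quercetin and 231 in quercetin plus LPS libraries.

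The second comparison asked which miRNAs differed in cultures given quercetin on days 5 and 7, without LPS. Both arms of miR-132 and miR-212, hairpins of a shared cluster that responds to CREB, fell. miR-212-3p went from 213 ± 61.2 CPM in control to 31.1 ± 4.80 in quercetin libraries (log2 fold change -2.78 ± 0.28, adjusted p = 7.9e-06), miR-212-5p changed by -2.57 ± 0.36, miR-132-5p by -1.99 ± 0.25 and miR-132-3p by -1.85 ± 0.26 (1326 ± 501 to 368 ± 59.5 CPM), all lower in 4 of 4 mice. miR-155-3p and miR-222-5p, which rose with LPS, were also lower with quercetin alone. The log2 fold change of miR-155-3p was -1.56 ± 0.34 (adjusted p = 0.00587) and that of miR-222-5p -1.66 ± 0.21 (adjusted p = 4.0e-05). The erythroid miRNA miR-451a rose from 18.1 ± 4.94 to 128 ± 33.2 CPM (2.83 ± 0.33, adjusted p = 2.9e-05). In all, 39 miRNAs were higher and 51 lower of 568, and 155 had an unadjusted p under 0.05.

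Among the largest rises were also miR-7033-5p (2.96 ± 0.31), miR-210-3p, a target of hypoxia signalling (2.87 ± 0.83, adjusted p = 0.0258), miR-215-5p (2.66 ± 0.28), miR-486a-5p with its identical copy miR-486b-5p (2.56 ± 0.46) and miR-5121 (1.74 ± 0.28). Smaller rises were seen for miR-320-3p, miR-29a-5p, miR-3057-5p, miR-677-5p and miR-455-5p, with log2 fold changes from 1.20 to 1.39. The other large falls were those of miR-3968 (-2.58 ± 0.42), miR-138-5p (-2.33 ± 0.54), miR-181b-1-3p (-2.21 ± 0.34), miR-342-5p (-1.83 ± 0.22), miR-147-3p, a TLR-responsive miRNA (-1.66 ± 0.30), and miR-221-5p (-1.42 ± 0.43). miR-155-5p (-0.14 ± 0.30, adjusted p = 0.813) and miR-146a-5p (-0.75 ± 0.64, adjusted p = 0.478) did not pass, and miR-146a-5p was at -0.13 without control 2.

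Of the LPS-induced list, 8 of 20 members fell and none rose over all miRNAs (9 fell when adjusted over the list alone), namely both arms of miR-132 and miR-212, miR-147-3p, miR-155-3p, miR-125a-5p and miR-222-3p. Of these, only miR-155-3p (2.00) had passed in LPS vs control. There miR-222-3p was at 1.14, miR-125a-5p at 0.35 and miR-147-3p at 0.08. In that comparison miR-212-5p was at 0.26, miR-212-3p at 0.10, miR-132-5p at -7.6e-04 and miR-132-3p at -0.07. Most of the members that fell were thus not seen to rise with LPS in these cells. The list was shifted down (camera adjusted p = 1.8e-04), with adjusted p = 0.0773 with an estimated correlation. Its median log2 fold change was -0.74, and -0.53 to -0.70 under the other scalings. The Dlk1-Dio3 cluster, a maternally expressed imprinted array of miRNAs that includes miR-369, rose in 5 of 12 members tested, and in 7 adjusted over the list alone (adjusted p = 8.0e-05; adjusted p = 0.0816 with an estimated correlation, and 0.0322 when the mouse was also a block). Its list names 95 members, most of which were not tested, so these counts do not describe the whole cluster. Its members miR-411-5p (1.26 ± 0.28), miR-410-3p (1.97 ± 0.46), miR-409-3p (2.08 ± 0.50) and miR-127-5p (2.41 ± 0.67) were all at low levels, and miR-369-3p went from 4.93 ± 2.40 to 14.2 ± 4.30 CPM (1.52 ± 0.43, adjusted p = 0.0231). A further member, miR-654-3p, is among the 4 rows left out. As deposited it was lower, against the rise of the cluster, at a mean of 0.25 counts in quercetin and 100.5 in control libraries (adjusted p = 5.0e-04), and the list of 13 had adjusted p = 0.00435 (adjusted p = 0.231 with an estimated correlation). With the columns of these rows put back it was not past the threshold (-0.81 ± 0.74, adjusted p = 0.534), and the list had adjusted p = 3.1e-04 (adjusted p = 0.0923 with an estimated correlation). The miR-23/27/24 clusters fell in 3 of 11 members, also adjusted over the list alone (adjusted p = 0.0399; adjusted p = 0.390 with an estimated correlation, and 0.0541 with the 4 rows as deposited), among them miR-27a-3p (-0.65 ± 0.19), miR-27a-5p (-1.30 ± 0.36) and miR-24-1-5p (-1.09 ± 0.32). miR-23a-5p did not pass (-0.84 ± 0.34).

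Beside these groups, the erythroid list, a marker set of another cell type, rose in 5 of 6 members, also adjusted over the list alone: miR-451a, miR-144-3p (2.89 ± 0.67), miR-144-5p (2.40 ± 0.60) and the identical miR-486a-5p and miR-486b-5p (adjusted p = 8.0e-05; adjusted p = 0.0507 with an estimated correlation, and 0.0322 when the mouse was also a block). miR-486a-3p did not pass (-0.0030 ± 0.66). The other 13 lists were not shifted relative to other miRNAs. By fry, which does not compare a list with other miRNAs, 3 of them lay lower on balance: miR-17-92 (adjusted p = 0.0138), granulocyte and monocyte (0.0280) and Sfmbt2 cluster miRNAs (0.0382). Members past the threshold over all miRNAs, higher and lower, numbered 0 and 1 of 8 in the list falling after TLR4 stimulation, 1 and 0 of 9 in let-7, 0 and 2 of 19 in miR-17-92, 0 and 1 of 10 in miR-15/16, 2 and 0 of 7 in miR-29 and 1 and 0 of 11 in miR-30. They numbered 1 and 1 of 8 in miR-181, 1 and 3 of 8 in miR-34/miR-210, 0 and 2 of 44 in the Sfmbt2 cluster, 0 and 2 of 9 in granulocyte and monocyte, 0 and 1 of 6 in lymphocyte, 1 and 0 of 17 in stromal and 0 and 0 of 3 in foreign tissue miRNAs. Adjusted over the list alone, the counts changed to 0 and 0 in miR-15/16, 2 and 1 in miR-29, 0 and 0 in miR-30, 2 and 4 in miR-34/miR-210 and 0 and 0 in stromal miRNAs.

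The count of 90 fell to 55 without quercetin replicate 3 and to 54 without quercetin replicate 4. With upper quartile scaling the split was 48 higher and 29 lower, as the median of all miRNAs moved from -0.05 to 0.15 on the log2 scale. Calls were lost for miR-369-3p without quercetin 1, 3 or 4 (adjusted p 0.0530 to 0.0596), miR-29a-5p without control 2 or 4 or quercetin 2 or 4 (0.0542 to 0.0591) and miR-127-5p without control 2 or 3 or quercetin 1 or 3 (0.0525 to 0.0719). miR-210-3p was lost without control 1, 2 or 3 or quercetin 2 or 3 (0.0533 to 0.0699) and with the mouse as a block (0.0563), and miR-221-5p without control 1, 2 or 3 or quercetin 2, 3 or 4 (0.0506 to 0.107). miR-27a-5p was lost without control 1 or 2 or quercetin 2, 3 or 4 (0.0550 to 0.0789), and miR-27a-3p and miR-24-1-5p without control 1 or 2 or any quercetin library (0.0531 to 0.120). The shift of the miR-23/27/24 clusters was lost without control 1, 2 or 3 or quercetin 1 or 4 (0.0566 to 0.0900).

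The third comparison asked what quercetin did to cells then given LPS. miR-212-3p fell from 228 ± 74.0 CPM in LPS to 22.4 ± 4.99 in quercetin plus LPS libraries (log2 fold change -3.35 ± 0.29, adjusted p = 1.2e-06), miR-212-5p by -2.97 ± 0.37, miR-132-5p by -2.17 ± 0.25 and miR-132-3p by -2.02 ± 0.26, all in 4 of 4 mice. The LPS-responsive miR-155-3p was at 556 ± 186 CPM with LPS and 231 ± 90.2 with quercetin plus LPS (-1.26 ± 0.34, adjusted p = 0.0147), and miR-222-5p at 409 ± 69.2 and 171 ± 24.8 CPM (-1.25 ± 0.21, adjusted p = 4.5e-04). miR-369-3p rose from 4.72 ± 2.21 to 18.6 ± 4.55 CPM (1.97 ± 0.43, adjusted p = 0.00483). The erythroid miR-451a rose from 17.1 ± 1.47 to 140 ± 65.5 CPM (3.03 ± 0.33, adjusted p = 1.7e-05). In all, 49 miRNAs were higher and 81 lower of 568, and 213 had an unadjusted p under 0.05.

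The largest rise was that of miR-143-3p, a miRNA of smooth muscle and fibroblasts (5.00 ± 1.34, adjusted p = 0.0147). It averaged 39.4 ± 17.7 CPM with LPS, and reached 65.3, 4317, 202 and 471 CPM in quercetin plus LPS replicates 1 to 4. Without replicate 2 its log2 fold change was 2.80 (adjusted p = 0.0669). The other large rises were those of miR-144-3p (3.29 ± 0.66), miR-215-5p (3.19 ± 0.28), miR-199a-3p with its identical copy miR-199b-3p (2.47 ± 0.68), miR-7033-5p (2.27 ± 0.30), miR-5121 (2.26 ± 0.29), miR-203-3p (2.03 ± 0.32), miR-29a-5p (1.61 ± 0.38) and miR-677-5p (1.499 ± 0.287). Large falls were those of miR-5107-5p (-3.33 ± 0.65), miR-3968 (-2.68 ± 0.42), miR-138-5p (-2.26 ± 0.54), miR-1249-3p (-2.14 ± 0.47) and miR-3473d (-2.08 ± 0.43). Falls of miR-702-3p, miR-351-5p and miR-99b-5p lay between -1.92 and -1.85. miR-155-5p (-0.29 ± 0.30, adjusted p = 0.546) and miR-146a-5p (-0.90 ± 0.64, adjusted p = 0.342) did not pass.

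The LPS-induced list fell in 10 of 20 members and rose in none over all miRNAs (11 fell when adjusted over the list alone; adjusted p = 9.2e-04), with adjusted p = 0.0884 with an estimated correlation. Its median log2 fold change was -1.08, and -0.70 to -0.93 under the other scalings. In addition to the 8 members that fell without LPS, miR-146b-5p and miR-99b-5p were lower. Neither of these had passed in LPS vs control (log2 fold change 0.50 and 0.51). The miR-23/27/24 clusters fell in 5 of 11 members, also adjusted over the list alone (adjusted p = 0.0249; adjusted p = 0.281 with an estimated correlation), among them miR-24-1-5p (-1.39 ± 0.33), miR-24-3p (-1.31 ± 0.31), miR-27a-5p (-1.43 ± 0.37) and miR-23a-5p (-1.54 ± 0.40). The Dlk1-Dio3 cluster rose in 6 of 12 members tested and in 8 adjusted over the list alone (adjusted p = 1.2e-04; adjusted p = 0.0884 with an estimated correlation, and 0.0407 when the mouse was also a block), with miR-411-5p at 1.65 ± 0.28, miR-410-3p at 1.88 ± 0.45 and miR-127-5p at 2.84 ± 0.73. As deposited, miR-654-3p was lower here too, at a mean of 0 counts in quercetin plus LPS and 109.5 in LPS libraries (adjusted p = 2.9e-04), and the list of 13 had adjusted p = 0.00307 (adjusted p = 0.206 with an estimated correlation). With the columns put back, miR-654-3p was at -1.69 ± 0.77 (adjusted p = 0.122) and the list had adjusted p = 0.00114 (adjusted p = 0.139 with an estimated correlation).

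Beside these groups, 2 lists of other cell types rose. The erythroid list rose in 5 of 6 members, also adjusted over the list alone (adjusted p = 1.2e-04; adjusted p = 0.0582 with an estimated correlation, and 0.0407 when the mouse was also a block), including miR-144-5p (2.86 ± 0.59) and miR-486a-5p (1.41 ± 0.44, adjusted p = 0.0320). The stromal, endothelial and epithelial list rose in 5 of 17 members, and in 7 adjusted over the list alone (adjusted p = 0.00341; adjusted p = 0.262 with an estimated correlation): miR-143-3p, miR-145a-5p (4.14 ± 1.08), miR-145a-3p (2.78 ± 0.61), miR-199a-3p and miR-199b-3p. In 12 lists there was no shift relative to other miRNAs. By fry, 5 of these lay lower on balance, namely miR-17-92 (adjusted p = 6.0e-04), miR-34/miR-210 (0.00267), Sfmbt2 (0.00270), miR-181 (0.0319) and granulocyte and monocyte miRNAs (0.0368), and 2 higher, miR-30 (0.0368) and foreign tissue miRNAs (0.0390). In these lists, members higher and lower over all miRNAs numbered 0 and 1 of 8 in the list falling after TLR4 stimulation, 1 and 0 of 9 in let-7, 0 and 3 of 19 in miR-17-92, 0 and 0 of 10 in miR-15/16, 2 and 0 of 7 in miR-29, 0 and 0 of 11 in miR-30 and 0 and 2 of 8 in miR-181. They numbered 0 and 3 of 8 in miR-34/miR-210, 0 and 5 of 44 in the Sfmbt2 cluster, 0 and 1 of 9 in granulocyte and monocyte, 0 and 1 of 6 in lymphocyte and 1 and 0 of 3 in foreign tissue miRNAs. Adjusted over the list alone, the counts changed to 0 and 0 in the list falling after TLR4 stimulation, 1 and 3 in miR-34/miR-210, 0 and 2 in lymphocyte and 2 and 0 in foreign tissue miRNAs.

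The balance of rises and falls moved with the scaling: 67 higher and 66 lower with RLE, 71 and 54 with the upper quartile and 75 and 50 with library size, where the median of all miRNAs was 0.01, 0.14 and 0.15 on the log2 scale against -0.13 with TMM. The count of 130 fell to 80 without LPS replicate 1 and to 81 without LPS replicate 2. miR-145a-5p was lost without quercetin plus LPS 2, where its log2 fold change was 2.43 (adjusted p = 0.0666), and was 4.76 without LPS 2. Calls were also lost for miR-143-3p with the mouse as a block (0.0577), miR-351-5p without LPS 2 (0.0581) and miR-24-1-5p without LPS 1 or 2 (0.0532 and 0.0701). miR-702-3p was lost without LPS 1, 2 or 3 or quercetin plus LPS 1, 2 or 4 (0.0950 to 0.165), and miR-99b-5p without LPS 1 or 2 or quercetin plus LPS 1 or 4 (0.1005 to 0.262). The log2 fold change of miR-99b-5p was -1.01 without LPS 2, that of miR-702-3p -2.60 without quercetin plus LPS 3, and that of miR-5107-5p -2.72 without quercetin plus LPS 4. miR-199a-3p and miR-199b-3p were at 1.80 without quercetin plus LPS 2 (adjusted p = 0.0496), miR-127-5p at 3.44 without LPS 3 and miR-144-5p at 3.47 without LPS 4. miR-24-3p was lost without LPS 1 or 2 or quercetin plus LPS 4 (0.0530 to 0.0739), miR-27a-5p and miR-23a-5p without LPS 1 or 2 or quercetin plus LPS 1 (0.0529 to 0.0726), and miR-486a-5p without LPS 3 or 4 or quercetin plus LPS 1 (0.0512 to 0.0536). The shift of the miR-23/27/24 clusters was lost without LPS 2 (0.0676), quercetin plus LPS 2 (0.0517) or quercetin plus LPS 3 (0.0609).

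The fourth comparison asked which miRNAs LPS moved in cells that had received quercetin. miR-222-5p rose from 58.2 ± 1.23 to 171 ± 24.8 CPM (log2 fold change 1.56 ± 0.21, adjusted p = 6.9e-04) and miR-155-3p from 46.9 ± 7.14 to 231 ± 90.2 CPM (2.30 ± 0.35, adjusted p = 0.00168), both in 4 of 4 mice. These 2 were the miRNAs past the threshold, and 0 fell by edgeR, with 41 at an unadjusted p under 0.05. DESeq2 called 4 higher and 0 lower, and limma-voom 2 higher and 0 lower. miR-203-3p (1.32 ± 0.31, adjusted p = 0.126), miR-221-5p (1.55 ± 0.43, adjusted p = 0.308) and miR-222-3p (0.88 ± 0.26, adjusted p = 0.347) did not pass, nor did miR-155-5p (0.31 ± 0.30, adjusted p = 0.742), miR-146a-5p (0.67 ± 0.63, adjusted p = 0.742) or miR-369-3p (0.39 ± 0.41, adjusted p = 0.790). Without quercetin 1, miR-146a-5p was at 1.29. None of the 17 lists was shifted (smallest camera adjusted p 0.141, smallest fry adjusted p 0.398), and in the LPS-induced list 1 of 20 members rose, or 2 adjusted over the list alone. Without quercetin replicate 4 the count was 7, and without quercetin plus LPS replicate 2 it was 4. Both calls held without any single library, with an edgeR adjusted p of at most 0.00834 for miR-155-3p and 0.00239 for miR-222-5p.

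The fifth question was whether the LPS effect differed with quercetin. No miRNA passed the interaction test by edgeR, DESeq2 or limma-voom (0 each), with 26 at an unadjusted p under 0.05 in edgeR. The smallest p-values belonged to miR-129-5p (-1.83 ± 0.56), miR-342-3p (-1.02 ± 0.33), miR-203-3p (1.25 ± 0.44), miR-3074-5p (-3.83 ± 1.39) and miR-374c-3p (1.34 ± 0.49), with an adjusted p of 0.889 for each. The value of miR-3074-5p, at 0.109 ± 0.146 CPM in controls, moved to -5.08 without control 1 and to -2.93 without LPS 2. The interaction of miR-155-3p was 0.30 ± 0.47 (adjusted p = 0.923) and that of miR-222-5p 0.40 ± 0.29 (adjusted p = 0.893). For miR-155-5p it was -0.15 ± 0.43, for miR-146a-5p -0.15 ± 0.89 (0.50 without quercetin 1) and for miR-369-3p 0.45 ± 0.60. The stromal, endothelial and epithelial list was shifted up as a set (camera adjusted p = 0.00720; adjusted p = 0.515 with an estimated correlation; smallest fry adjusted p of any list 0.533), with 0 of 17 members past the edgeR test over all miRNAs or adjusted over the list alone. That shift was lost without control 3 (adjusted p = 0.0957), LPS 3 (0.0869), quercetin 4 (0.0568), quercetin plus LPS 2 (0.1004) or quercetin plus LPS 4 (0.0849).

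Across 568 miRNAs, the quercetin effect without LPS correlated with the effect with LPS (Pearson r = 0.76, jackknife SE 0.23, Spearman rho = 0.74), for comparisons with no library in common but the same 4 mice. miRNAs are not independent replicates, so these values describe the relation. Of the 90 miRNAs called without LPS, 89 had the same sign with LPS, and of the 130 called with LPS, 127 had the same sign without it. Called in both were 25 higher and 39 lower miRNAs, where independent lists would share 3.36 and 7.27, and 0 were called in opposite directions. For the LPS effect without and with quercetin, r was 0.07 (jackknife SE 0.39) and rho 0.0071. At such an error r does not settle whether the LPS effects are related. All 3 miRNAs called in the first kept their sign in the second, and miR-155-3p and miR-222-5p were called in both.

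**Figure D3:**
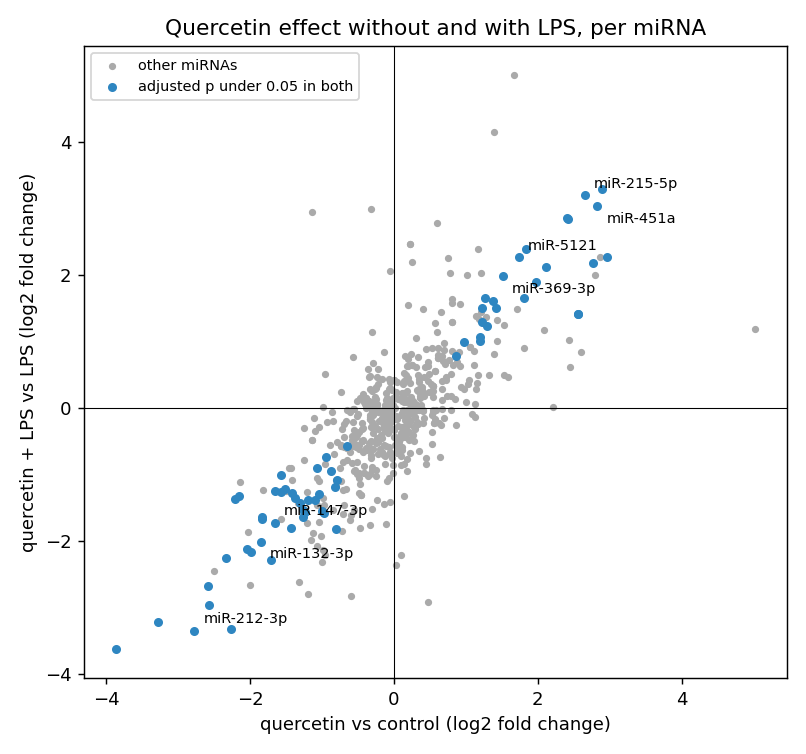
Log2 fold change of quercetin vs control (horizontal axis) against quercetin plus LPS vs LPS (vertical axis) for each of 568 miRNAs. Blue points passed an adjusted p of 0.05 in both (25 higher and 39 lower), and grey points did not. miR-212-3p lies at -2.78 and -3.35, and miR-451a at 2.83 and 3.03.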

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

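The tests of erythroid RNA, depth, GC content, columns put back and other splits of the samples in this part were chosen after the results were seen, and that of rows at other distances after the pattern but before its own result.

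Names left out of the comparisons held large counts in the quercetin libraries. miR-6993-3p averaged 6607.5 counts in quercetin and 0 in control libraries, while its neighbour in the table, miR-1839-5p, averaged 0.50 and 7172, and miR-700-3p averaged 45.25 and 0, against its neighbour miR-654-3p with 0.25 and 100.5. A candidate explanation is that columns of neighbouring rows were exchanged when the table was put together. The scan that found these 2 pairs was repeated on rows farther apart, and 0 of 100 other distances held as many passing pairs (at most 1), so such pairs were more frequent among neighbours than elsewhere, though they are few. The pairs were picked for matching the controls once exchanged, so their tests with the columns put back (0 of 4 called in edgeR, 1 at an unadjusted p under 0.05) are no separate evidence, and no biological explanation was tested.

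Of the 6 erythroid miRNAs tested, 5 (2 of them identical copies) rose with quercetin, with and without LPS, although red cells were lysed before culture, per the labels, and the shift of the list had adjusted p = 0.0507 and 0.0582 without and with LPS with an estimated correlation. The member that did not pass, miR-486a-3p, is the other arm of the miR-486a hairpin and had 230 counts over all libraries. RNA of erythroid cells at a higher share in the quercetin cultures may account for the rises, and such a source would add its miRNAs in 1 ratio. The rise of miR-486a-5p was 3041 ± 948 CPM (SE) and that of miR-451a 110 ± 16.8 CPM without LPS, and 1356 ± 450 and 122 ± 32.8 CPM with LPS. The log2 ratios of these rises differed by 1.32 ± 0.79 (SE), within 2 SE. That SE takes both miRNAs and all groups as independent, though they share libraries and mice. This test, which is also weak at such an error, does not exclude a shared source. A change of these miRNAs within the dendritic cells by quercetin, the group the design names, stays open too and was not tested.

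The count of miRNAs moved by quercetin could come from the lower depth of those libraries or from a trend on hairpin GC content. After thinning to the smallest library, 76 of 90 calls remained in the same direction without LPS and 99 of 130 with LPS. After removal of the GC trend 79 of 90 and 104 of 130 remained, where any called miRNA without a GC value counted as lost. Most calls thus needed neither. Without LPS, however, fold changes hardly related to GC content (r = -0.01), so removal of the trend tests little there. Other splits of the 8 libraries gave at most 1 call without LPS and 3 with LPS, and 1 of 35 splits, the real split, reached 90 and 130. This is the smallest share that 35 splits can give, with libraries taken as unrelated. No other split of these libraries came near such counts. A shift in cell makeup with quercetin stays open for these calls.

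The 3 calls in LPS vs control were reached by 1 of 35 splits (highest other 1). This is the smallest share that 35 splits can give, with libraries taken as unrelated and no adjustment over comparisons. For these reasons the splits alone do not exclude chance for this count. Each of the 3 was also lost without some single library. In those fits the log2 fold change stayed at 1.72 to 2.03 for miR-155-3p, 0.98 to 1.16 for miR-222-5p and 1.93 to 2.23 for miR-129-5p. miR-155-3p and miR-222-5p, but not miR-129-5p, were also called in quercetin plus LPS vs quercetin, which uses other libraries of the same mice. Of the splits of quercetin plus LPS vs quercetin, 2 of 35 gave at least 2 calls and the highest other gave 7. The splits thus do not exclude chance for that count, though both of its calls held without any single library. Only 8 of the 35 splits part the libraries of all 4 mice as labelled, too few for a share under 0.05. Among these the real split gave 3, 90, 130 and 2 calls in the 4 comparisons, and the others gave 0 in edgeR. For the interaction the real count was 0, so 100 of 100 drawn splits gave at least as many whatever the data, and the splits do not test it. The highest gave 75. The splits with 75, 63 and 45 calls placed 0, 4 and 0 of the 4 quercetin labels and 3, 1 and 3 of the 4 quercetin plus LPS labels where the real split has them, so they set the quercetin effect of one arm against its mirror in the other, a structure of the samples.

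The stromal, endothelial and epithelial list differed between the effects with and without LPS as a set (camera adjusted p = 0.00720; adjusted p = 0.515 with an estimated correlation). Libraries far from the rest of their group, by the gap over the range of log2 CPM, were seen for miR-199a-3p and its identical copy miR-199b-3p in quercetin plus LPS 2 (0.985), miR-29a-5p in quercetin plus LPS 1 (0.942), miR-99b-5p in quercetin 4 (0.916), miR-369-3p in quercetin 2 (0.912) and control 2 (0.852), miR-146a-5p in quercetin 1 (0.912), miR-3057-5p in quercetin 2 (0.868), miR-3074-5p in quercetin 2 (0.852) and miR-7033-5p in LPS 3 (0.851). These are 10 of 200 groups tested, where 10 would pass by chance.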

How the results depend on the processing

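Chosen after the data were seen were thinning, removal of the hairpin GC trend, sample weights, the block with control 3 and control 4 exchanged, collapsed identical names, the left-out names as deposited or put back, and leaving out each mouse. For the values below that moved, the cause was not tested, except that fewer miRNAs or libraries entered where a filter, a group or a library was dropped.

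Of 152 recomputed counts of calls, 117 stayed within 1.5 times the reported count. The 3 calls of LPS vs control became 1 with library size scaling, 6 with DESeq2, 5 with the GC trend removed and 6 with sample weights, and 0 to 2 without a library. The 90 of quercetin vs control ranged from 44 to 76 without a library or a mouse, 44 being without mouse 2. The 130 of quercetin plus LPS vs LPS became 72 with a filter of 10 CPM in 4 samples and 70 with only the groups compared, and ranged from 56 to 133 without a library or a mouse. The 2 of quercetin plus LPS vs quercetin became 4 with DESeq2, 4 with the GC trend removed and 4 with that and the replicate block, and 1 to 7 without a library or a mouse. With the replicate block alone the counts were 3, 92, 144, 2 and 0 for the interaction, and with control 3 and control 4 exchanged in it 4, 115, 181, 4 and 0. The interaction count was 0 in each alternative run, DESeq2 and limma-voom included, with 26 at an unadjusted p under 0.05 in edgeR.

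Lists shifted in camera numbered 0 in LPS vs control, 0 in quercetin vs control, 0 in quercetin plus LPS vs LPS and 0 for the interaction with an estimated correlation, against 1, 4, 5 and 1. The block gave 2 in LPS vs control, where leaving out a library gave 0 to 3, and for the interaction leaving out a library gave 0 to 4. Apart from that list, miR-210-3p, miR-143-3p and the estimated-correlation values given with the comparisons, the block changed no call of a named miRNA or list. With control 3 and control 4 exchanged in the block, 2 lists were shifted in LPS vs control, and miR-222-3p in LPS vs control (edgeR adjusted p = 0.0426) and miR-203-3p in quercetin plus LPS vs quercetin (0.0476) passed. With the correlation also estimated, the Dlk1-Dio3 and erythroid lists then had adjusted p = 0.0566 without LPS and 0.0551 with LPS. The counts of 4 of 4 mice given for miRNAs held under this exchange.

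The correlation of the LPS effect without and with quercetin (r = 0.07) ranged from -0.15 to 0.31 without a library or a mouse. It was -0.07 without control 2, -0.05 without LPS 4, -0.02 without quercetin plus LPS 1 and -0.15 without mouse 4. Of 2997 recomputed values of named miRNAs, 2734 kept direction and side of the threshold, 205 lost a call, 23 gained a call and 35 changed sign, all 35 in miR-369-3p, miR-155-5p or miR-146a-5p where none was called. miR-369-3p in LPS vs control was 0.031 with limma-voom and -0.44 to 0.083 without a library or a mouse. miR-155-5p in quercetin vs control was 0.067 with upper quartile scaling, 0.0072 with library size and -0.28 to 0.085 without a library. It ranged from -0.48 to 0.054 in quercetin plus LPS vs LPS, -0.067 to 0.61 in quercetin plus LPS vs quercetin and -0.32 to 0.16 for the interaction. The interaction of miR-146a-5p was 0.059 with upper quartile scaling, 0.14 with the replicate block, 0.0058 with the left-out names put back and -0.62 to 0.68 without a library or a mouse.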

Other observations

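The test of passenger arms after LPS was written before the result was seen; the relation to GC content and the miRNAs of the next paragraph, with their tests, were chosen after the values were seen.

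From the X-linked miR-106a/363 cluster, a paralogue of miR-17-92, miR-106a-5p and miR-20b-5p fell with quercetin both without and with LPS, and the cluster's other tested members did not pass. miR-106a-5p changed by -1.19 ± 0.24 (log2, SE, n = 4, edgeR adjusted p = 0.00287) and -1.38 ± 0.24 (7.3e-04), and miR-20b-5p by -1.38 ± 0.27 (0.00259) and -1.36 ± 0.27 (0.00253). In the same order, miR-18b-5p was at -0.84 ± 0.35 and -0.20 ± 0.34, miR-363-3p at -0.57 ± 0.35 and -0.52 ± 0.35 and miR-363-5p at -0.98 ± 0.57 and -1.35 ± 0.55 (edgeR adjusted p 0.0817 to 0.738). The list of miR-17-92 and its paralogues was not shifted relative to other miRNAs (camera adjusted p = 0.314 and 0.222). The near-identical relatives of miR-106a-5p and miR-20b-5p, miR-17-5p (-0.26 ± 0.19 and -0.27 ± 0.19) and miR-20a-5p (-0.21 ± 0.24 and -0.03 ± 0.24) did not pass in edgeR (adjusted p 0.328 to 0.943), and reads could be shared between such names, a point that was not tested. miR-342-5p fell by 1.83 ± 0.22 and 1.67 ± 0.22. These calls of miR-106a-5p, miR-20b-5p and miR-342-5p held under RLE, upper quartile and library size scaling and without each of the 8 libraries in turn. miR-342-3p, the other arm, changed by -0.80 ± 0.23 without LPS, a call lost without control 3, quercetin 1 or quercetin 4 (edgeR adjusted p 0.0566 to 0.0865) and with upper quartile (0.0861) or library size scaling (0.0559), and by -1.82 ± 0.24 with LPS. miR-29c-5p rose by 0.87 ± 0.22 and 0.77 ± 0.22 and let-7c-5p by 0.97 ± 0.27 and 0.99 ± 0.27, but without control 4 the calls without LPS were lost (0.0655 and 0.0572). Of the miR-34b/c hairpins, which respond to p53, miR-34c-3p changed by -0.98 ± 0.25 without LPS, a call lost without 3 of 8 libraries and with upper quartile scaling (edgeR adjusted p = 0.0753). With LPS it changed by -1.59 ± 0.25 (edgeR adjusted p = 3.5e-04), which held under the other scalings and without each of the 8 libraries. The calls of miR-34b-3p and miR-34c-5p were less stable, and miR-34b-5p, also tested, did not pass over all miRNAs in either comparison. miR-34b-3p (-0.88 ± 0.25 and -0.95 ± 0.25) was lost without 5 of 8 libraries in the absence of LPS and 4 of 8 in its presence, and miR-34c-5p (-1.07 ± 0.29 and -0.90 ± 0.29) without 3 and 7 of 8. Neither miR-34b-3p nor miR-34c-5p passed with upper quartile or library size scaling (edgeR adjusted p 0.0518 to 0.187), nor miR-34c-5p with LPS under RLE (0.0623).

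A hypothesis fixed before the data were examined was that, soon after LPS, the passenger arm of newly transcribed hairpins moves more than the long-lived guide arm. Hairpins are measured in the same libraries and are not independent replicates, so the intervals and p-values here describe the spread over hairpins, not over mice. Over 13 hairpins of the LPS-induced list with both arms tested, the less abundant arm changed by 0.28 more than the other arm in LPS vs control (log2, bootstrap 95% interval -0.03 to 0.62, two-sided sign permutation p = 0.141), and 9 of 13 differences were above 0. The stated sign of failure was an interval that spans 0, which it does. Such an interval also holds differences of the size sought, so the hypothesis and its absence cannot be told apart with 13 hairpins. In quercetin plus LPS vs quercetin the difference was 0.49 (interval 0.07 to 0.92, sign permutation p = 0.0513). In quercetin vs control it was -0.37 (sign permutation p = 0.0488) and in quercetin plus LPS vs LPS -0.17 (sign permutation p = 0.317), and these 4 p-values are not adjusted. Over all 150 hairpins the difference was -0.08 in LPS vs control, opposite in sign to that of the list, -0.22 in quercetin vs control, -0.16 in quercetin plus LPS vs LPS, close to the -0.17 of the list, and -0.018 in quercetin plus LPS vs quercetin.

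Across 546 miRNAs, fold changes related to hairpin GC content with r = -0.47 in quercetin plus LPS vs quercetin, -0.35 for the interaction, -0.24 in quercetin plus LPS vs LPS, -0.02 in LPS vs control and -0.01 in quercetin vs control. miRNAs are not independent replicates, so these values describe the relation.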
